A study of Mus musculus with 6 samples.

How the data were processed

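Poly-A RNA was sequenced from pancreatic islets of 7-week-old mice in 2 groups of 3 samples, and each sample pooled the islets of 3 mice. The control group was Wtap flox/flox, in which the Wtap gene carries recombination sites but is intact, and the other group carried the label Wtap-βKO, a deletion of Wtap meant for insulin-producing β cells. Per the labels' protocols the RNA was captured with poly-T beads, copied with random primers and sequenced in pairs on an Illumina NovaSeq, with no step that marks the strand. The labels call the 3 samples of a group independent biological replicates.

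The authors deposited one table of FPKM values, fragments per kilobase of gene scaled to sequencing depth, with one column per sample. The deposited table also gave a gene length in bases for each gene, per the file headers, and the annotation behind it is not given in the sources used here. Per the submitters' processing notes the tools were CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the builds GRCm38 and mm10, and the notes give no role or order for them. The table held 54532 genes, of which 29669 were above 0 in at least 1 sample. GENCODE M21 held 54495 of the gene identifiers, and 53548 of these had the same coordinates, which are given here on GRCm38.

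Each FPKM value multiplied by the gene length was a whole multiple of the worth of 1 read, within 0.01 read, for 100.0% of values. The recovered reads came to between 16353297 and 18682745 per sample. The library size implied by the worth of 1 read differed from the sum of recovered reads by a factor of 0.936 to 1.05, so the deposited FPKM already carried a scaling between samples. A median-of-ratios factor computed from the deposited values was 1.01 in every sample, so the planned rescaling changed nothing between samples.

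Genes with a mean FPKM of at least 0.5 over the 6 samples were tested, 15927 in all. Values were analysed as log2(scaled FPKM + 1), so fold changes given on the log2 scale understate the change of genes with low values. The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05, and all adjusted p-values for single genes come from it. Fold changes are the libraries labelled Wtap-βKO over or minus the controls, and folds are ratios of mean scaled FPKM. Values are given as mean ± SD over 3 samples, and SE is the standard error of the log2 fold change as moderated by limma. It draws on a variance trend over all genes as well as on the gene's own replicates. Single values such as the insulin share were compared with a two-sided exact permutation test, for which 3 against 3 samples cannot give a p under 0.1. Counting floors of 3 reads cover counting error only, since reads from PCR libraries are not independent molecules.

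The 33 gene lists, the rule for named genes, the test and most alternatives were fixed before the data were examined. The rule named Wtap and its writer complex, 8 islet genes (Ins1, Ins2, Pdx1, Mafa, Slc2a2, Gcg, Sst and Ppy), and the 10 largest rises and 10 largest falls among called genes with no overlap between the groups and a mean scaled FPKM of at least 5 in the higher group. Predicted gene models and pseudogenes were left out of these. The rule also named up to 4 members of each list with the smallest adjusted p and a mean scaled FPKM of at least 1. Genes named outside the rule are marked as such, and a few genes that the rule names are not reported here. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, again with a correlation estimated from the data, and with fry, all in limma, with adjustment over the 33 lists. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes.

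The scripts were tested on simulated data made from the mean values of the 6 samples, with 15918 genes fitted. Of genes changed 1.5-fold, 28 of 100 were called, and of genes changed 2-fold, 54 of 100 were called. All 82 called changed genes had the right direction, and 4 of 15719 unchanged genes were called. Every pair of samples within a group differed by more than sampling noise, with a chi-square per degree of freedom between 5.06 and 16.4, so no sample was counted as a copy of another.

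The alternatives were FPKM as deposited, quantile normalization, rescaling without the 50 genes with the highest means, pseudocounts of 0.1 and 0.5, no filter on low values, a mean FPKM of at least 5, no variance trend, a robust variance trend, limma voom on the recovered reads, the replicate number as a block, protein-coding genes alone, and leaving out each sample in turn. Scaling to total recovered reads and the removal of a trend with gene length and GC content were added after the data were seen. Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 read the table, and matplotlib 3.10.9 drew the figures.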

Results

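The series compared the messenger RNA of pancreatic islets between control mice and mice labelled as lacking Wtap in β cells. WTAP is a subunit of the nuclear complex that writes N6-methyladenosine (m6A) on RNA, and the series asks what it does in β cells. The comparison had 6 libraries, 3 controls and 3 labelled Wtap-βKO, with between 16353297 and 18682745 recovered reads each. The libraries of each group resembled their own group more than the other in all 6 cases.

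Wtap itself was not lower in the libraries labelled Wtap-βKO. It lies on chromosome 17 from 12966796 to 12994169 on the minus strand (GRCm38). The recovered Wtap reads were 1154, 1125 and 1284 in control replicates 1 to 3, and 1316, 1329 and 1321 in replicates 1 to 3 labelled Wtap-βKO. Mean scaled FPKM was 11.1 ± 0.541 (SD, n = 3) in controls and 11.7 ± 0.548 (SD, n = 3) in the libraries labelled Wtap-βKO, a log2 fold change of 0.07 (SE 0.063, adjusted p = 0.475 by limma). The value covers every exon of the gene in every islet cell type, and the labels do not say which part was deleted, so it may check nothing. Directions below are therefore those of the libraries as labelled.

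Of 20 β-cell hormones and maturity markers, 14 fell in the libraries labelled Wtap-βKO (camera adjusted p = 1.60e-11, and adjusted p = 0.0907 with an estimated correlation). Mafa, a transcription factor of mature β cells, fell from 353 ± 33.4 to 48.6 ± 6.60 scaled FPKM (n = 3 each), 7.26-fold. Slc2a2, which encodes the glucose transporter GLUT2, fell 5.34-fold, and Ins1, one of the insulin genes, fell 2.57-fold, from 42597 ± 4324 to 16545 ± 1716. The α-cell-enriched transthyretin gene Ttr rose 2.06-fold and Aldh1a3, which marks dedifferentiated β cells, 24.2-fold. Of 25 measured genes of cholesterol and fatty acid synthesis, 20 fell (camera adjusted p = 1.05e-13, and adjusted p = 0.194 with an estimated correlation).

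**Figure D1:**
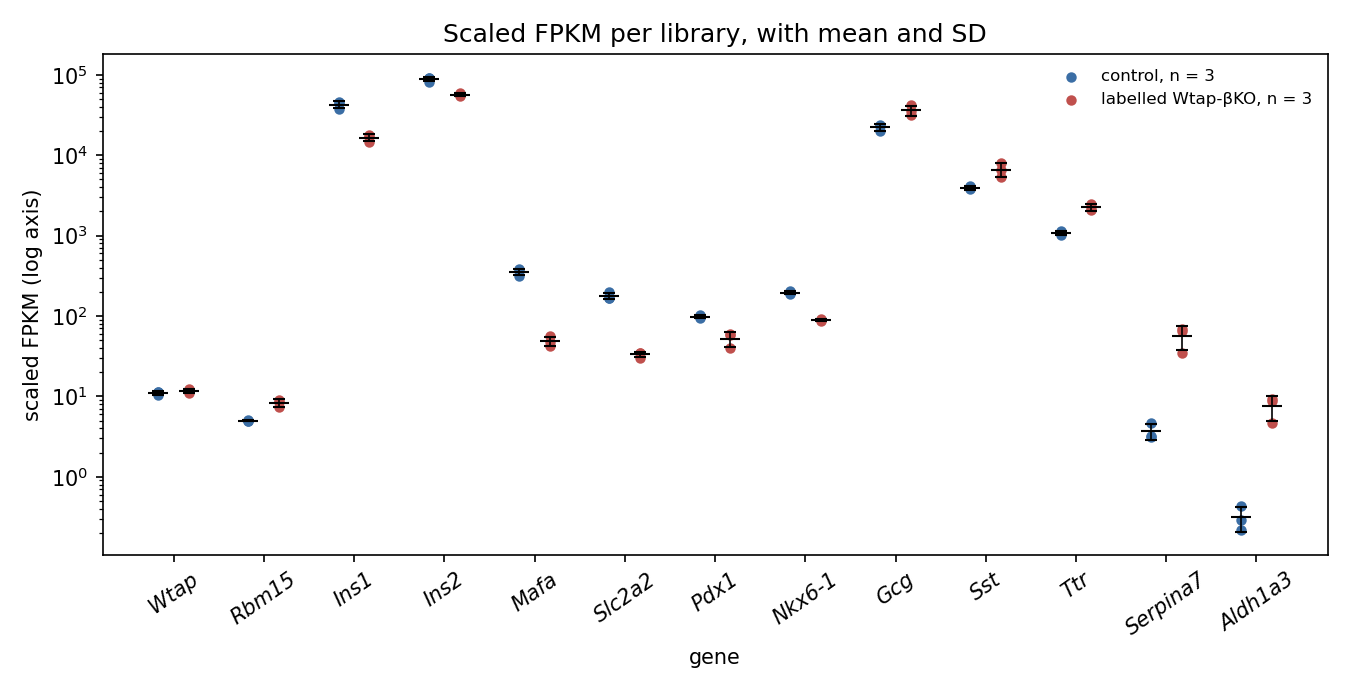
Scaled FPKM (vertical log axis) of 13 genes (horizontal axis) in each of the 3 control libraries (blue) and the 3 libraries labelled Wtap-βKO (red), with horizontal bars at the mean and error bars of 1 SD. Wtap lies at 11.1 and 11.7, while Mafa drops from 353 to 48.6 and Aldh1a3 rises from 0.312 to 7.55.

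By limma, 1397 genes rose and 1798 fell of 15927 tested, and 121 rose and 164 fell at least 2-fold. The groups did not overlap for 6574 genes, 41.3% of those tested, where chance gives 10%. The split depended on the scaling. Of the called genes 43.7% were higher, against 53.8% (1676 higher and 1440 lower) after rescaling without the 50 highest genes and 68.1% (2334 higher and 1094 lower) when scaled to total recovered reads, which moved the median of all genes up by 0.09 on the log2 scale. Leaving out control replicate 1, 2 or 3 gave 804, 774 and 854 higher genes and 1039, 1048 and 1055 lower ones, and leaving out replicate 3 labelled Wtap-βKO gave 829 and 1152. The first principal component (49.5% of the variance) separated the groups, and the second (16.2%) set replicate 2 labelled Wtap-βKO apart. Without that replicate 1384 genes were higher and 1862 lower.

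Of the 10 genes with the largest rises by the naming rule, 5 were immunoglobulin genes. Igha, the constant region of IgA, rose from 0.469 ± 0.355 to 17.1 ± 1.03 (39, 5 and 22 reads in the controls; log2 fold change 3.65, SE 0.17, adjusted p = 0.000121), and Igkc, the kappa constant region, rose from 4.15 ± 0.837 to 45.5 ± 4.23. Iglv1, Iglc1 and Ighv1-26 had no read in any control, so against a floor of 3 reads over the control group they were at least 56.2-fold, 52.5-fold and 34.1-fold higher. Without replicate 3 labelled Wtap-βKO the first 2 bounds were 26.5-fold and 23.9-fold, and without control replicate 1 or 3 all 3 were lower by over 1.5 times (down to 36.7-fold, 34.2-fold and 22.2-fold), as the floor of 3 reads then covered 2 libraries. Leaving out any 1 of the 3 controls ended the calls of Iglv1 and Iglc1, with adjusted p from 0.0522 to 0.0542. Pigr, the receptor that carries polymeric IgA across epithelia, rose 10.8-fold. Serpina7, which encodes thyroxine-binding globulin, rose 15.3-fold, Aldh1a3, a retinaldehyde dehydrogenase, 24.2-fold, and the collagen gene Col20a1 7.77-fold. Mir7k showed the largest log2 rise (4.36, SE 0.49, adjusted p = 0.00215), on 10 control reads in all, 7 of them in replicate 3, and poly-A libraries do not capture mature microRNA. Variable-region genes of one family, such as that of Ighv1-26, and the lambda constant genes are similar in sequence, so their reads may be split between copies.

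The largest fall was that of Trpm5, a calcium-activated cation channel of β cells, from 26.8 ± 2.22 to 1.07 ± 0.664 (log2 fold change -3.79, SE 0.20, adjusted p = 0.000169), with replicate 2 of that group at 1.84 and the others at 0.658 and 0.720. Cyp4f39, a fatty acid hydroxylase gene, fell 18.6-fold, Gad1, which makes GABA, 7.88-fold (11.99-fold without replicate 2 labelled Wtap-βKO), and Cox6a2, a cytochrome oxidase subunit of muscle type, 6.04-fold. Fam151a fell 5.56-fold, Prss53 5.05-fold, and the granule protein gene Sytl4 4.82-fold. Mafa and Slc2a2 were also among the 10, and Mir344i, another microRNA gene, fell by 2.81 on the log2 scale (log2 fold change -4.34 with a pseudocount of 0.1). Trpm5, Gad1, Cox6a2, Slc2a2, Fam151a, Prss53, Pdx1 and Col20a1 overlap another annotated gene, as do these genes named elsewhere: Mettl3, Rbm15b, Neurod1, Scg3, Atp2a2, Pclo, Ttr, Cd81, Bhlhe41, Zfp36l1, Ctrb1, Spp1, Egfl7, Eng, Atf5, Atf6, Ccnd2, Cdk4, Cdc20, Pklr, mt-Nd4, mt-Nd2, Srebf1, Lss and Ptbp1. The library protocol does not mark strand and the counting mode is not given in the sources used here, so their values are uncertain to that extent.

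Among β-cell hormones and maturity markers, 14 of 20 measured members fell (14 adjusted over the list alone), with a median log2 fold change of -1.32. Papss2, a sulfate donor synthase, fell from 174 ± 10.8 to 42.2 ± 1.07, Tmem215 fell 4.77-fold and the phosphatase inhibitor gene Ppp1r1a 3.22-fold. The list was lower than other genes by camera (adjusted p = 1.60e-11), but adjusted p = 0.0907 with an estimated correlation. Ins2 was 88739 ± 5845 in controls and 56429 ± 2373 in the libraries labelled Wtap-βKO, with every value of one group apart from the other (log2 fold change -0.65, SE 0.31), and did not pass the test (adjusted p = 0.189 by limma; 5.21e-05 to 1 over its alternatives). The replicates of Ins2 spread far less than the groups differed, and its SE draws on the variance trend over all genes. Its failed test thus does not show it unaltered. The call of Ins1 (adjusted p = 0.00866) was lost without a filter on low values (0.831) and without control replicate 2 (0.0544). Both insulin genes together took 31.2% ± 2.02 of total FPKM in controls and 19.0% ± 0.183 in the libraries labelled Wtap-βKO (exact permutation test, p = 0.1, the smallest that 3 against 3 samples allow).

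Of 19 measured β-cell transcription factors, 10 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 4.64e-05, and adjusted p = 0.0907 with an estimated correlation). Nkx6-1 fell 2.18-fold, Pdx1 1.88-fold, Neurod1 1.54-fold and Myt1 1.44-fold. Of 19 genes of glucose sensing and membrane excitability, 10 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 5.54e-05, and adjusted p = 0.0907 with an estimated correlation). The calcium pump genes Atp2a2 and Atp2a3 fell by 1.26 and 0.99 on the log2 scale. Of 18 genes of incretin and G protein receptor signalling, 8 fell and 1 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.00830, and adjusted p = 0.200 with an estimated correlation). The fatty acid receptor gene Ffar1 fell 3.17-fold, the incretin receptor gene Glp1r 2.79-fold and the muscarinic receptor gene Chrm3 2.23-fold. Of 24 genes of the exocytosis machinery, 10 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.000427, and adjusted p = 0.0907 with an estimated correlation). The active-zone gene Pclo fell 1.99-fold.

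Secretory granule genes went both ways. Of 18 genes of proinsulin processing and dense-core granules, 8 rose and 4 fell (8 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0567). The granin genes Chgb, Scg3 and Scg5 rose 1.75-fold, 1.76-fold and 1.68-fold, while Slc30a8, the zinc transporter of insulin granules, fell 1.91-fold.

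**Figure D2:**
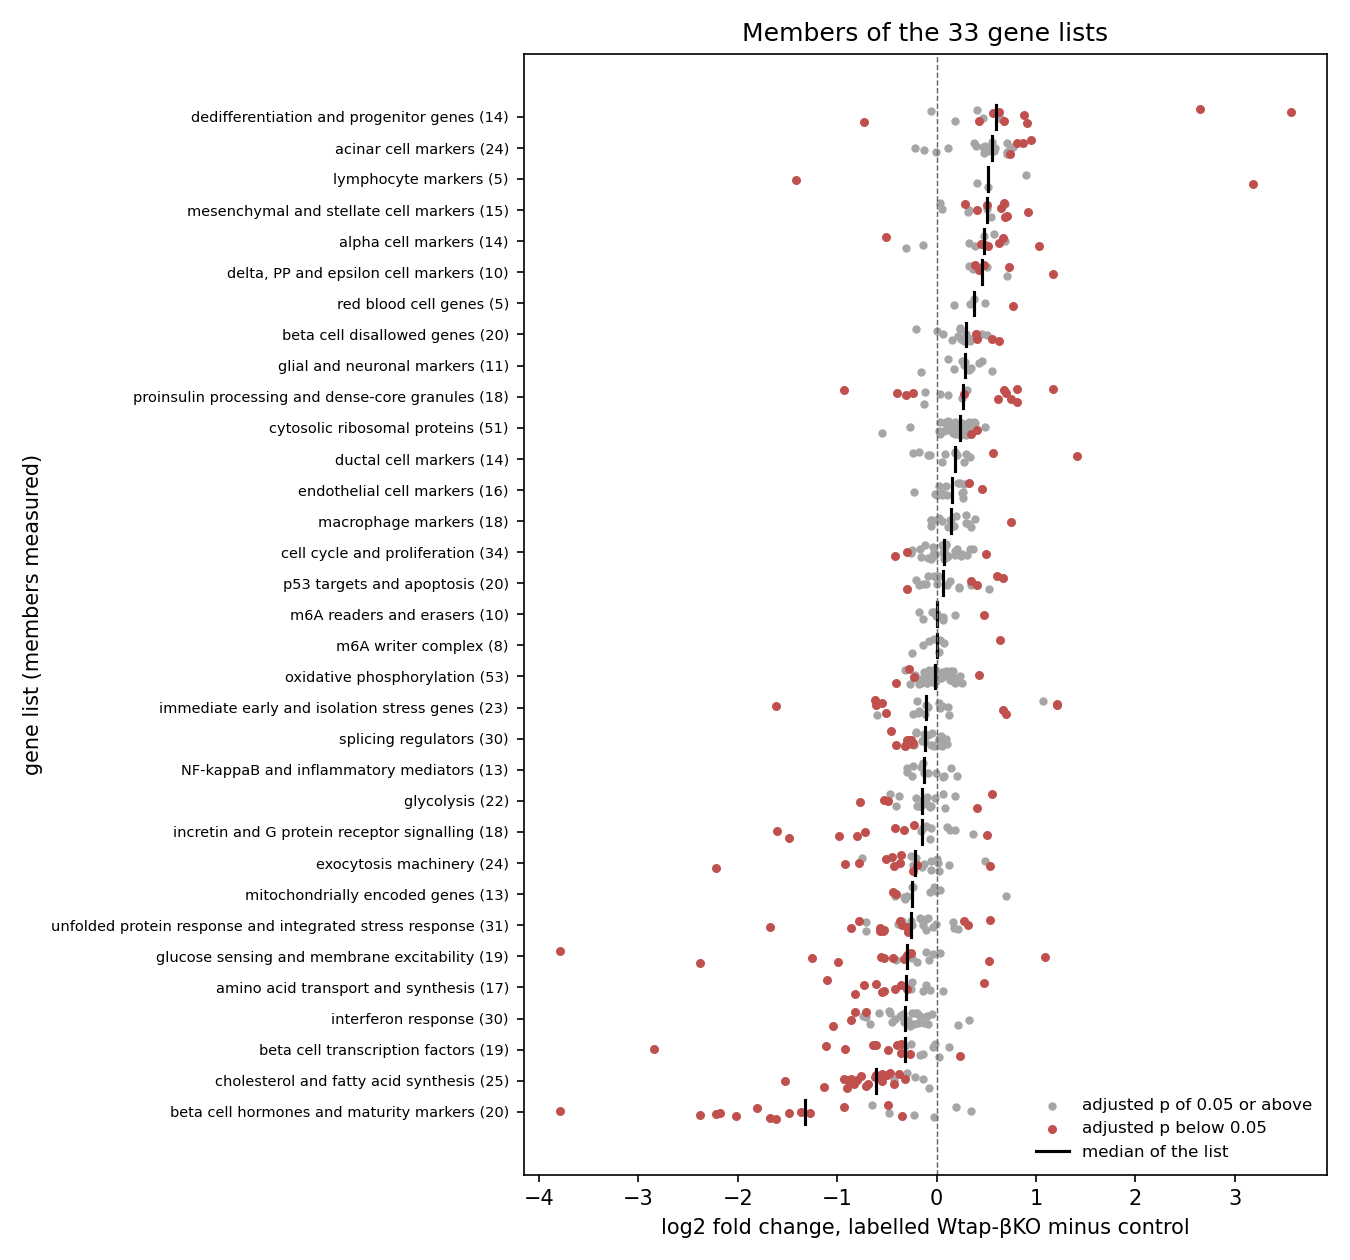
Log2 fold change, labelled Wtap-βKO minus control (horizontal axis), of each measured member of the 33 gene lists (rows, ordered by the median of the list, with the number measured). Red points have an adjusted p under 0.05, grey points do not, and the black bar is the median of the list, from -1.32 for β-cell hormones and maturity markers to 0.60 for dedifferentiation and progenitor genes.

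Some markers of other islet endocrine cells were higher. Of 14 measured α-cell markers, 6 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00276, and adjusted p = 0.355 with an estimated correlation). Ttr rose from 1090 ± 63.1 to 2241 ± 232. Gcg, the glucagon gene, was 22339 ± 2107 and 36137 ± 5200 (log2 fold change 0.69, SE 0.24, adjusted p = 0.0888 by limma), and it was called higher in 9 of its 20 alternatives, with adjusted p from 0.000319 to 0.925. Of 10 δ-, PP- and ε-cell markers, 5 rose (7 adjusted over the list alone; camera adjusted p = 1.00e-04, and adjusted p = 0.226 with an estimated correlation). Sst, the somatostatin gene, rose 1.68-fold (adjusted p = 0.0263, lost without a filter on low values (0.557), without replicate 3 labelled Wtap-βKO (0.0736) and without control replicate 1, 2 or 3 (0.0829, 0.106 and 0.0733)), and Fgf12 rose 2.41-fold. Ppy, the pancreatic polypeptide gene, was 9030 ± 637 and 12500 ± 6024, a difference within the spread between replicates (adjusted p = 0.455). It rested on replicate 2 labelled Wtap-βKO, at 19446 against 9359 and 8697 in the others of its group, and without it the log2 fold change was 0.00069.

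Of 14 dedifferentiation and progenitor genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 5.79e-05, and adjusted p = 0.245 with an estimated correlation). Serpina7 and Aldh1a3 led it, Cd81 rose 1.62-fold, and the circadian repressor gene Bhlhe41 fell 1.84-fold. Of 20 genes kept low in normal β cells (disallowed genes), 4 rose (7 adjusted over the list alone; camera adjusted p = 0.000326, and adjusted p = 0.285 with an estimated correlation). These were Ldha, lactate dehydrogenase A (1.58-fold), Igfbp4 (1.70-fold), the hexokinase gene Hk1 (1.53-fold) and Zfp36l1 (1.45-fold). The calls of Igfbp4, Hk1 and Zfp36l1 were lost in 4, 6 and 9 of 19 alternatives each, with adjusted p up to 0.0649, 0.118 and 0.134. The values cover all islet cell types. Neither the rises of disallowed genes nor those of dedifferentiation genes are thus shown to lie in β cells.

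Some markers of exocrine, stromal and immune cells were higher. Of 15 mesenchymal and stellate cell markers, 8 rose (11 adjusted over the list alone; camera adjusted p = 1.06e-05, and adjusted p = 0.297 with an estimated correlation), with Col3a1 2.04-fold and Mgp 1.68-fold. Of 24 acinar markers, 4 rose (9 adjusted over the list alone; camera adjusted p = 0.000142, and adjusted p = 0.460 with an estimated correlation), among them the trypsinogen gene Try5 (from 14.3 ± 3.17 to 28.5 ± 5.80) and Ctrb1 (1.80-fold), whose calls were lost in 3 and 9 of 20 alternatives (adjusted p up to 0.0537 and 0.127). The acinar count was 13 without control replicate 3, 3 without replicate 3 labelled Wtap-βKO, 2 without replicate 2 and 1 without replicate 1 of that group, and no member was called without control replicate 1 or 2, against 13 members at an unadjusted p under 0.05 and 11 by limma voom on all 6 libraries. Of 16 endothelial markers, 2 rose, Egfl7 (1.43-fold) and Eng (1.26-fold), with camera adjusted p = 0.0215 and adjusted p = 0.460 with an estimated correlation. The calls of Egfl7 and Eng were lost in 7 and 9 of 20 alternatives (adjusted p up to 0.1005 and 0.111), that of Egfl7 without any 1 library other than replicate 2 labelled Wtap-βKO and that of Eng without any 1 of the 6 libraries. Adjusted over the list alone, limma called 0 endothelial markers, against 6 at an unadjusted p under 0.05 and 3 by voom. Of 18 macrophage markers, Lyz2 rose 1.83-fold (1 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.460 with an estimated correlation). Of 5 red blood cell genes, Hbb-bs rose 1.75-fold (4 adjusted over the list alone; camera adjusted p = 0.00909, and adjusted p = 0.248 with an estimated correlation). Of 14 ductal markers, Spp1 and Clu rose, by 1.41 and 0.57 on the log2 scale (2 adjusted over the list alone; camera adjusted p = 0.128). Of 5 lymphocyte markers, Igkc rose and Cd79a, a B-cell receptor subunit gene, fell 3.24-fold (4 and 1 adjusted over the list alone; camera adjusted p = 0.0567). Of 11 glial and neuronal markers, limma called 0, against 4 higher at an unadjusted p under 0.05 and 4 by voom (0 adjusted over the list alone; camera adjusted p = 0.0172, and adjusted p = 0.460 with an estimated correlation).

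Of 25 genes of cholesterol and fatty acid synthesis, 20 fell (21 adjusted over the list alone; camera adjusted p = 1.05e-13, and adjusted p = 0.194 with an estimated correlation), with a median log2 fold change of -0.61. Srebf1, the transcription factor that drives lipid synthesis, fell from 39.3 ± 0.818 to 20.1 ± 0.883, the desaturase gene Scd2 fell 2.95-fold, Insig1 2.24-fold and the lanosterol synthase gene Lss 1.99-fold. Of 17 genes of amino acid transport and synthesis, 9 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.000142, and adjusted p = 0.0907 with an estimated correlation), with Cbs 2.27-fold and the transporter gene Slc7a5 1.68-fold lower. Of 31 genes of the unfolded protein and integrated stress responses, 11 fell and 3 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.00360, and adjusted p = 0.364 with an estimated correlation). Atf5 fell 3.13-fold, Edem1 1.87-fold and Atf6 1.47-fold. Of 30 interferon response genes, 4 fell (3 adjusted over the list alone; camera adjusted p = 6.00e-04, and adjusted p = 0.460 with an estimated correlation), with Oas2 2.33-fold and Ifit3b 2.64-fold lower. The call of Oas2 was lost in 6 of 19 alternatives (adjusted p up to 0.0737). The interferon count was 14 without replicate 2 labelled Wtap-βKO and 1 without any other single library.

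Of 51 cytosolic ribosomal protein genes, limma called 2 higher, Rps7 (1.34-fold) and Rplp1 (1.27-fold, but lower under quantile normalization), and 0 adjusted over the list alone, against 19 at an unadjusted p under 0.05 and 14 by voom (camera adjusted p = 5.94e-06, and adjusted p = 0.460 with an estimated correlation). The calls of Rps7 and Rplp1 were lost or turned in 5 and 8 of 20 alternatives (adjusted p up to 0.0805 and 0.412). The ribosomal count was 23 when scaled to total recovered reads and 14 without replicate 1 labelled Wtap-βKO, and the median of 0.24 came to 0.11 without replicate 2 of that group. Of 30 splicing regulators, 9 fell (9 adjusted over the list alone; camera adjusted p = 0.00360, and adjusted p = 0.294 with an estimated correlation), with the splicing repressor gene Ptbp1 1.38-fold and Luc7l2 1.35-fold lower.

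In the m6A writer complex, Rbm15, which recruits the complex to RNA, rose 1.67-fold, from 4.97 ± 0.0770 to 8.31 ± 0.875 (adjusted p = 0.00347), the 1 called member of 8 (1 adjusted over the list alone; camera adjusted p = 0.766). Mettl14 was 3.71 ± 0.187 and 2.98 ± 0.337 (adjusted p = 0.0918; 0.0404 to 0.246 over its 19 alternatives), and the catalytic subunit gene Mettl3 4.72 ± 0.343 and 4.26 ± 0.893 (adjusted p = 0.510). Virma, Zc3h13, Rbm15b and Cbll1 had log2 fold changes of 0.03, 0.03, -0.07 and -0.03, none past the threshold. Of 10 readers and erasers, Ythdf2, whose protein promotes decay of m6A-marked RNA, rose 1.45-fold (1 adjusted over the list alone; camera adjusted p = 0.485).

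The other lists did not pass camera. Of 20 p53 target and apoptosis genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.140), with Phlda3 1.81-fold and Bcl2l1 1.59-fold higher, the latter call lost in 2 of 20 alternatives (adjusted p up to 0.0656). Of 34 cell cycle genes, Cdc20 rose and Ccnd2 and Cdk4 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.600). The calls of Cdc20 and Cdk4 were lost in 5 of 19 and 6 of 20 alternatives (adjusted p up to 0.0880 and 0.0949), Cdc20 without control replicate 2 or 3 or replicate 1 or 3 labelled Wtap-βKO, and Cdk4 without any 1 library other than replicate 2 of that group. Of 23 immediate early and isolation stress genes, 4 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.665), with Hspb1 2.45-fold higher and Egr1 1.53-fold lower. Of 22 glycolysis genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.0798), with Pklr 1.96-fold lower. Of 53 genes of oxidative phosphorylation, 1 rose and 3 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.936, which had the opposite sign to the median of -0.01), with Uqcrfs1 1.35-fold higher and Sdha 1.33-fold lower. Of 13 mitochondrially encoded genes, mt-Nd4 and mt-Nd2 fell 1.33-fold and 1.35-fold (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0748). The call of mt-Nd4 was lost in 3 of 20 alternatives (adjusted p up to 0.153), among them without control replicate 2 or 3, and that of mt-Nd2 in 10 of 20 (up to 0.229), among them without any 1 of the 6 libraries. Of 13 NF-κB and inflammatory genes, limma called 0, against 2 lower at an unadjusted p under 0.05 and 1 by voom (0 adjusted over the list alone; camera adjusted p = 0.333). In all, camera called 21 of 33 lists, 11 higher and 10 lower. At the same preset correlation it called 7 to 16 lists in splits of the libraries that mixed the groups. A camera call at that correlation alone is therefore weak evidence of a difference between the groups. With an estimated correlation between genes camera called 0 lists (7 at an unadjusted p under 0.05). Fry, which asks whether the members move on balance one way, called 18, of which 15 were also called by camera.

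The counts of called members depended on the setting for most lists. Over all alternatives, members called lower numbered 12 to 16 for β-cell maturity, 16 to 21 for cholesterol and fatty acid synthesis, 7 to 11 for β-cell transcription factors (0 to 2 higher), 8 to 11 for glucose sensing (2 higher) and 5 to 9 for incretin signalling (0 to 3 higher). They numbered 4 to 13 for exocytosis (1 to 2 higher), 5 to 15 for the stress responses (0 to 5 higher), 5 to 12 for amino acids (0 to 1 higher), 1 to 14 for the interferon response (0 to 1 higher) and 2 to 10 for splicing regulators. Members called higher numbered 5 to 9 for granules (2 to 4 lower), 5 to 9 for α cells (1 to 2 lower), 3 to 7 for δ, PP and ε cells, 6 to 10 for dedifferentiation (1 lower) and 1 to 9 for disallowed genes. They numbered 0 to 13 for acinar, 2 to 3 for ductal (0 to 1 lower), 0 to 6 for endothelial, 4 to 12 for mesenchymal, 1 to 5 for macrophage, 1 to 3 for lymphocyte (1 lower), 0 to 4 for glial and 1 to 4 for red blood cell genes, and 0 to 23 for ribosomal proteins. Higher and lower members numbered 2 to 6 and 0 to 1 for p53 and apoptosis, 0 to 3 and 1 to 3 for the cell cycle, 3 to 5 and 3 to 7 for immediate early genes, and 1 to 2 and 1 to 5 for glycolysis. They numbered 1 to 9 and 1 to 5 for oxidative phosphorylation, 0 to 1 and 0 to 6 for mitochondrially encoded genes, 1 to 3 and 0 to 1 for m6A readers and erasers, and 1 and 0 to 1 for the writer complex, and lower NF-κB genes 0 to 3.

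Several counts were smaller when 1 library was left out and fewer samples entered the test. Leaving out control replicate 1, 2 or 3 gave 4, 6 and 4 lower exocytosis genes, 6, 5 and 6 lower and 0, 0 and 1 higher genes of the unfolded protein and integrated stress responses, and 2, 2 and 5 lower splicing regulators. It also gave 2, 1 and 1 higher disallowed genes, 3 higher δ-, PP- and ε-cell markers each time, and 2 lower granule genes each time. Without replicate 1 labelled Wtap-βKO there were 5 lower exocytosis genes, 7 lower stress response genes, 4 lower splicing regulators and 1 higher disallowed gene. Without replicate 3 of that group there were 6 lower exocytosis genes, 3 lower splicing regulators, 1 higher disallowed gene and 3 higher δ-, PP- and ε-cell markers. Mesenchymal markers called higher numbered 5 without control replicate 1 or 2 or without replicate 1 or 3 labelled Wtap-βKO. Lower incretin and receptor genes numbered 5 without control replicate 1 or 2 or replicate 3 labelled Wtap-βKO, and lower amino acid genes 5 without control replicate 3. Genes of oxidative phosphorylation numbered 5 higher without replicate 1 labelled Wtap-βKO, 5 lower without replicate 2 of that group and 1 lower without any other single library, and 5, 5 and 9 were higher under quantile normalization, after rescaling without the 50 highest genes and when scaled to total recovered reads. Higher p53 and apoptosis genes numbered 2 without control replicate 1 or 3, and lower immediate early genes 3 without control replicate 1 or 3 or replicate 1 or 2 labelled Wtap-βKO. The camera calls of the lists of β-cell maturity, β-cell transcription factors, glucose sensing and cholesterol and fatty acid synthesis held in all 6 of these fits. The call of the endothelial list was lost without control replicate 2 (adjusted p = 0.150) or replicate 3 labelled Wtap-βKO (0.0835), that of the macrophage list without replicate 2 of that group (0.0555) and with the length and GC trend removed (0.0532), and that of the glial list without control replicate 2 (0.0622). The splicing regulators were not called under quantile normalization (0.0689), when scaled to total recovered reads (0.0951) or with the length and GC trend removed (0.0652), and the incretin list was not called at a mean FPKM of at least 5 (0.0735). Without replicate 2 labelled Wtap-βKO camera also called the granule (0.0280), lymphocyte (0.0387), cell cycle (0.0387) and glycolysis (0.0150) lists. The granule list was also called without control replicate 3 (0.0418), under quantile normalization (0.0404), after rescaling without the 50 highest genes (0.0320), at a mean FPKM of at least 5 (0.0275), by voom (0.0110), with the replicate block (0.0409) and when scaled to total recovered reads (0.0309). The mitochondrially encoded list was called without control replicate 1 (0.00782), under quantile normalization (0.00918), after rescaling without the 50 highest genes (0.0491), by voom (0.0158), with the replicate block (0.0355) and when scaled to total recovered reads (0.0443). The lymphocyte list was called without control replicate 1 (0.0405), and with no filter on low values the lymphocyte (0.00198), ductal (0.0373) and glycolysis (0.0373) lists were, the last also with the replicate block (0.0409).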

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

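Scaling to total recovered reads, the removal of the length and GC trend, and the wish to see every count without replicate 2 labelled Wtap-βKO came after the data were seen. FPKM as deposited differed from the scaled values by one factor for all samples and so tested nothing. Scaling to total recovered reads gave 2334 higher and 1094 lower genes. The ratio of recovered reads to the implied library size was 1.01 to 1.05 in controls. It was 0.936 to 0.965 in the libraries labelled Wtap-βKO, so this scaling raised their values against the controls. Why the ratio differed between the groups was not tested. Leaving out 1 library in turn gave 774 to 1384 higher and 1039 to 1862 lower genes, with fewer samples to test. Genes higher at least 2-fold numbered 269 and 191 with pseudocounts of 0.1 and 0.5, which shrink low genes less, 299 by limma voom, and 56 and 71 with fewer genes tested (mean FPKM of at least 5, and protein-coding genes). Genes lower at least 2-fold numbered 297 with a pseudocount of 0.1, 306 by voom and 94 at a mean FPKM of at least 5. With an estimated correlation camera called 0 lists (7 at an unadjusted p under 0.05, and 18 by fry). The difference in insulin share was -5.98 percentage points of recovered reads against -12.3 of FPKM, since FPKM divides by the short length of these genes. With the replicate number as a block, 1148 genes were higher and 1490 lower, and camera also called the granule (adjusted p = 0.0409), glycolysis (0.0409) and mitochondrially encoded (0.0355) lists. The correlations of same-numbered samples' deviations were low, at 0.03, 0.04 and 0.02, but every sample correlated best with its own number. The latter is a hint from the data and not the design. The labels name no shared animal or day, so a pairing of the samples is neither shown nor excluded. Among genes that did not pass the test, the log2 fold change ran from -0.24 to 0.0045 for Mettl3 with 1 library left out (turning without replicate 3 labelled Wtap-βKO). It ran from -0.015 to 0.094 for Zc3h13 (turning without replicates 3 and 1 of that group, the latter at -0.0028), and turned to 0.032 for Rbm15b when scaled to total recovered reads. Cbll1 turned to 0.0061 without the 50 highest genes and 0.065 when scaled to total recovered reads, and ran from -0.056 to 0.023 with 1 library left out (turning without replicate 2 labelled Wtap-βKO). Of the called genes named, Rplp1 turned to -0.070 under quantile normalization. The median of the cell cycle list turned to -0.16 at a mean FPKM of at least 5 and ran from -0.012 (without replicate 1 labelled Wtap-βKO) to 0.14 with 1 library left out. The immediate early list ran from -0.17 to 0.022, turning without replicate 2 labelled Wtap-βKO. The test of oxidative phosphorylation changed sign at medians of -0.014 (no filter, the replicate block and fry), -0.052 (length and GC trend removed) and -0.060 to 0.054 with 1 library left out. The causes of these turns were not tested. Wtap kept a log2 fold change between 0.03 and 0.17 over its 20 alternatives, with adjusted p from 0.0678 to 0.806. At this depth the simulated test called 28 of 100 genes changed 1.5-fold. The simulation held far fewer changed genes than the 3195 called here, which makes the adjustment stricter, so its share is not that of the real test. A gene that was not called is still not shown to be unaltered.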

Other observations

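The tests of explanations and hypotheses in this part, the gene lists made for them, the splits of the libraries and the scaling to total recovered reads were chosen after the results were seen, while the comparison by limma, the fixed lists and the other scalings were planned. The genes Txnip, Arrdc4, G6pc2, Fasn, Acaca, Acly, Iapp, Jchain, Sdc1, Irf4, Derl3, Prdm1, Cd8a, Ms4a1, Cd3e, Tph1 and Cish lie outside the naming rule and were chosen after their values were seen.

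The arrestin family genes Txnip and Arrdc4 rose in the libraries labelled Wtap-βKO. Txnip, which encodes a thioredoxin-binding protein induced by glucose, rose from 150 ± 17.8 to 352 ± 34.7 (n = 3 each; log2 fold change 1.23, adjusted p = 0.000851 by limma), and Arrdc4 from 7.51 ± 0.190 to 19.3 ± 4.66 (log2 fold change 1.23, adjusted p = 0.00334). Both are targets of the glucose-responsive factor ChREBP. For the hypothesis of a higher ChREBP activity across islet cells, a rise of at least 4 of 8 other targets was the prediction, set after the results were seen. Of these, limma found 0 higher and 5 lower (Pklr, G6pc2, Fasn, Acaca and Acly), and camera on the list of 10 targets gave a direction of lower values with adjusted p = 0.0749, and adjusted p = 0.321 with an estimated correlation. A general rise of these targets was thus not seen. This does not decide on ChREBP activity, because G6pc2 is also in the list of β-cell maturity. Fasn, Acaca and Acly are also in that of cholesterol and fatty acid synthesis, and both lists were already found lower.

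The fall of β-cell maturity genes was weighed first. If all 20 members were made in β cells alone, a lower share of β cells as its whole cause would lower them by one fold. The 95% interval of 16 members excluded the median of the list, where 1 would be expected. This count alone cannot decide, because members also made in other cells would fall less, and falls of low genes are shrunk on this scale. Of 2 high genes, Slc2a2 fell by 2.38 on the log2 scale (95% interval of the change -2.59 to -2.17) and Ins1 by 1.36 (-1.91 to -0.82), so they did not share one fold. Trpm5 fell by 3.79 on the log2 scale while Iapp, the amylin gene of β cells, was 13070 and 12864 scaled FPKM (adjusted p = 0.935). Scaling between libraries left the median of the list at -1.21 or lower under every scaling run. As the whole cause of the rises of other cell types' markers, a lower β-cell share would raise these alike. The mean log2 rise of α-cell markers exceeded that of endothelial markers by 0.23 (SE 0.049, from differences within each library). Mean rises ran from 0.15 (endothelial) to 0.55 (δ, PP and ε cells), with α at 0.38, mesenchymal at 0.49 and acinar at 0.51. The pseudocount shrinks rises of low genes such as Egfl7 (7.00 in controls) more than those of high ones such as Ttr. This pair, chosen after the results were seen, therefore cannot decide. How far a change in the share of β cells gave these falls and rises stays open, as does the genotype on the labels.

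The level of Wtap was weighed next. The lower end of the 95% interval of its log2 fold change was -0.080, which at the control mean corresponds to a loss of 5.88% of islet Wtap reads. Within that interval, a loss of all Wtap reads in β cells would require that β cells give at most about 5.88% of islet Wtap reads. That share was not measured, so such a loss is limited by these values but not excluded. A deletion of a small part of the gene that leaves the rest transcribed cannot be told apart from none, since gene values do not show single exons. An exchange of 1 library between the groups is argued against, since 0 libraries resembled the other group more than their own. An exchange of all the labels would leave each library with its own group, so these values do not bear on it.

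The immunoglobulin genes were weighed last. Their reads numbered 151 to 208 in each of the 3 controls and 1900 to 2309 in each of the 3 libraries labelled Wtap-βKO, with 17 to 24 variable-region genes of at least 5 reads in the latter and 1 to 2 in the former. Of 37 immunoglobulin genes tested, 17 rose and 2 fell by limma. Plasma cells in the preparations are a candidate source. Of 10 other plasma cell genes, 3 (Jchain, Sdc1 and Irf4) had every library labelled Wtap-βKO above every control, with Jchain at 48 reads in controls and 544 in the others, but Derl3 (1150 reads in controls and 650 in the others) and Prdm1 (469 and 369), neither of which passed the test, lay lower, and camera on the list gave adjusted p = 0.403. Lymphoid tissue or blood lymphocytes carried along were not excluded either, with 124 reads of 10 B- and T-cell genes in controls and 227 in the libraries labelled Wtap-βKO, of which Cd8a had 5 and 28 and Ms4a1 1 and 0. With Cd79a added, which fell (599 and 196 reads), the sums were 723 and 423, the other way round, and Cd79a at that level beside 4 control reads of Cd3e may come from other islet cells. Derl3 and Prdm1, with far more control reads than Jchain, may also come from other islet cells and so weigh little against plasma cells. Plasma cells stay open because the members of their list went both ways, and lymphocytes because most of their genes had few reads and Cd79a went the other way. The genotype as a cause of such cells was not tested.

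A growth hormone minigene, which some insulin-promoter Cre lines carry and which raises Tph1 in islets, was examined as a hypothesis because the Cre line is not given in the sources used here. Tph1 had 6 reads in controls and 1 in the libraries labelled Wtap-βKO, and the list of 7 response genes gave a camera adjusted p = 0.748, although Cish rose (log2 fold change 0.51, adjusted p = 0.0151). No rise of Tph1 was thus seen, where the minigene predicts one. The minigene is not excluded, because this rests on 1 gene near the floor and Cish rose.

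With 10 splits of the 6 libraries, a share under 0.05 cannot be reached. The real split, 1 of the 10, gave the highest count each time. It called 3195 genes and the highest other split 1, and it called 285 genes at least 2-fold and the highest other split 1. Camera at the preset correlation called 21 lists, and 7 to 16 in the other splits. Each other split had libraries of both groups on both sides. The difference between the groups thus added to the spread within each side, so few called genes were bound to follow. The contrast of 3195 with 1 is therefore no measure of chance.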
